A study of Mus musculus with 4 samples.

How the data were processed

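The data are SPLiT-seq counts (Parse Evercode WT v2) from mouse lung. Per the labels, lungs were perfused and digested, red cells were lysed, CD45-positive cells were depleted and EpCAM-positive cells enriched with magnetic beads, and live cells were sorted. The 4 samples are sublibraries, each of which mixes 1 pooled suspension of 6 Cre_Pos mice and 1 of 6 Cre_Neg mice, told apart by the first barcoding well. The deposited values are counts: the authors give a matrix of whole transcripts (UMIs) per barcode and gene without normalization, and a cell table with genes, transcripts and mapped reads per barcode. The lowest barcode has 10 UMIs, so the matrix is not filtered to cells. The other deposited columns hold no measurement but names: the barcode with its sublibrary, the pool, the first-round well, and the gene symbols. The labels name the genome build GRCm39, while the deposited gene table names its genome mm10, so no coordinates are given; the aligner and counter are not given in the sources used here.

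UMI sums and gene numbers of the matrix were checked against the cell table and were equal in all 647296 barcodes, as were the pool names and the well ranges. The matrix held 191160309 UMIs over 57010 genes, and 147 symbols stood on 2 or more gene identifiers. Cells were kept with at least 500 genes and at most 15% mitochondrial UMIs, which left 16579 and then 16541 barcodes. Scrublet, run per sublibrary, called 185 doublets (1.12%), which left 16356 cells. Kept cells held 87.6% of the Cre_Neg and 87.3% of the Cre_Pos UMIs.

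Counts were normalised per cell and log transformed, and 2999 variable genes, 30 principal components and 15 neighbours gave 41 clusters with the Leiden method at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, matplotlib 3.10.9). A marker passed in a cluster when its CPM plus 10 was at least 4 times that of the median cluster plus 10 and at least 10% of cells had a UMI. A cluster took the type with the largest share of passing markers, with at least 3, out of 37 marker sets. It stayed unnamed if its 10 leading genes held more markers of another lineage, or if its median UMI count was low with no marker of its type among its leading genes. This left 35 named and 6 unnamed clusters, and the 3 types of blood endothelium among them were merged. The class names carry "-like" because they rest on these markers alone. On simulated clusters, 37 of 37 types were named as simulated and 10 of 10 clusters without raised markers stayed unnamed. Every marker of a simulated type was raised far past the 4-fold limit, so this checked the working of the rule and not the class names of the real cells.

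The cell filters, marker sets, 25 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The thresholds for naming clusters, the merging of types into classes, the percentiles 1 and 99 taken as low and high for a list, the sex calls and the counting of cluster 4 as airway were set after seeing the data. Sex was called per cell from UMIs of Xist against those of 4 Y-linked genes (Ddx3y, Kdm5d, Eif2s3y and Uty).

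With 1 pool per genotype no p-value, SE or count of changed genes was computed. Shares have exact (Clopper-Pearson) 95% intervals, counts exact Poisson intervals, and ratios the exact conditional binomial interval for 2 Poisson counts. All cover counting error only, since cells of 1 pool are not independent animals and cells were not traced to mice. Gene ratios are log2 ratios, Cre_Pos over Cre_Neg, of UMIs summed over the cells of a class and divided by the UMIs of the class, in the 8 classes and unnamed clusters with at least 100 cells in each pool. A pool at 0 UMIs was set to a floor of 3 counts. Named genes had at least 100 UMIs, a log2 ratio of at least 1 in size and the same sign in the 4 sublibraries by their counts (0 UMIs in 1 pool counted as lower), and were ranked by the interval bound nearest 0: 10 each way in AT2- and ciliated-like cells and 3 each way elsewhere, leaving out mitochondrial, ribosomal, sex-linked and haemoglobin genes. Of each list described, the 2 highest and 2 lowest members and those differing at least 2-fold in AT2- and ciliated-like cells were added. In the other classes fewer list members are given, and a few genes that the rule names are left out of the text. Tek, Ptprb and members named beyond that rule were chosen after their values were seen. List medians cover members with at least 20 UMIs and are given as a percentile of 10000 random lists of the same size, each member drawn from the 100 genes nearest in expression; this describes these libraries and is not a test. The basal cell and haemoglobin lists had too few measured members in AT2- and ciliated-like cells for a median.

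On simulated counts at the observed depths, the interval covered the true ratio for 95.1% of 11140 genes in AT2-like and 95.9% of 10863 genes in ciliated-like cells. Unchanged genes passed the naming rule in 0.00914% and 0.488%, and genes with a true log2 ratio of 2 in 100% and 98.4%. The simulated counts held counting error only, with no added spread between cells, sublibraries or animals. These rates are therefore not rates of wrongly named genes in the real counts, where such spread can add to them. Alternatives were at least 1000 genes, at most 5% mitochondrial UMIs, no doublet removal, Leiden resolutions 0.5 and 2, leaving out each sublibrary, median-of-ratios scaling, cells weighted alike, thinning to 2000 UMIs per cell (1000 for classes called by markers), other UMI minimums for list members, and all barcodes without a filter for Trp73. Added after seeing the data were the values within Xist-only and within Y-only cells, cluster 4 counted as airway, and the airway share at resolution 0.5. Differences between single mice were not analysed here, because the counts do not tell the mice of a pool apart.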

Results

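The lungs of mice that carried Shh-Cre and floxed Trp73 (Cre_Pos) were compared with those of littermates homozygous for the floxed allele without Cre (Cre_Neg) by SPLiT-seq, a combinatorial barcoding method for single-cell RNA. Shh-Cre acts in the lung epithelium, and the floxed allele removes exons 7 to 9 of Trp73, which encodes the p53 family transcription factor p73. Each genotype was 1 pooled suspension of 6 mice at 8 weeks of age, depleted of CD45-positive cells and enriched for EpCAM-positive cells before barcoding. Both pools ran through the same 4 sublibraries, which were technical aliquots of the pools and made up 1 group of 4 samples. The sublibraries are also called replicates 1 to 4 below, and they are not replicate animals or pools. With 1 pool per genotype no test was possible, and all intervals are 95% intervals that cover counting error only.

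The counts held 647296 barcodes and 191160309 transcripts (UMIs), and 16356 barcodes were kept as cells, against the 20000 cells stated by the study. The Cre_Neg pool gave 7696 cells with a median of 8713.5 UMIs and 2824 genes, and the Cre_Pos pool gave 8660 cells with a median of 8219 UMIs and 2662 genes. Kept cells held 80279069 UMIs in Cre_Neg and 86915171 in Cre_Pos. Cre_Neg cells numbered 2075, 2093, 2056 and 1472 in sublibraries 1 to 4, with median depths of 7484, 9808, 7927 and 10201 UMIs. Cre_Pos cells numbered 2325, 2392, 2294 and 1649, with median depths of 7084, 8931.5, 7500 and 10368 UMIs.

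The first comparison asked where Trp73 transcripts were found and whether their level differed with Cre. Trp73 was 7.29-fold lower in the Cre_Pos pool over all kept cells: 6890 UMIs (interval 6728 to 7055) or 85.8 CPM in Cre_Neg against 1023 UMIs (961 to 1088) or 11.8 CPM in Cre_Pos, a log2 ratio of -2.87 (-2.96 to -2.77). Most of these UMIs lay in ciliated-like cells, with 6588 UMIs in Cre_Neg and 699 in Cre_Pos, and within that class the level was alike, at 334 CPM (326 to 342) and 316 CPM (293 to 340). In deuterosomal-like cells, the precursors that amplify centrioles before cilia form, Trp73 was at 473 CPM in Cre_Neg and 349 CPM in Cre_Pos, a log2 ratio of -0.44 (-0.69 to -0.18). The direction was not the same in both sexes: cells with Xist UMIs only were at 558 and 322 CPM. Those with Y-linked UMIs only were at 289 CPM (19 UMIs) and 526 CPM (48 UMIs). A Trp73 UMI was seen in 94.4% of Cre_Neg and 95.8% of Cre_Pos ciliated-like cells, at median depths of 15752 and 16849.5 UMIs. In AT2-like cells, the surfactant-producing alveolar type 2 class, used as the background for this measure, the shares were 0.121% and 0.367%, at median depths of 11695 and 14607.5 UMIs. After thinning every cell to 2000 UMIs, the shares in ciliated-like cells were 46.7% and 41.9%, and no AT2-like cell of either pool had a Trp73 UMI. Secretory-like cells held 1 Trp73 UMI in each pool. UMIs from parts of the gene outside the floxed exons still count, so these levels do not show whether the allele was recombined. The log2 ratio over all kept cells was -2.51, -3.16, -2.44 and -3.61 in the 4 sublibraries.

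**Figure D1:**
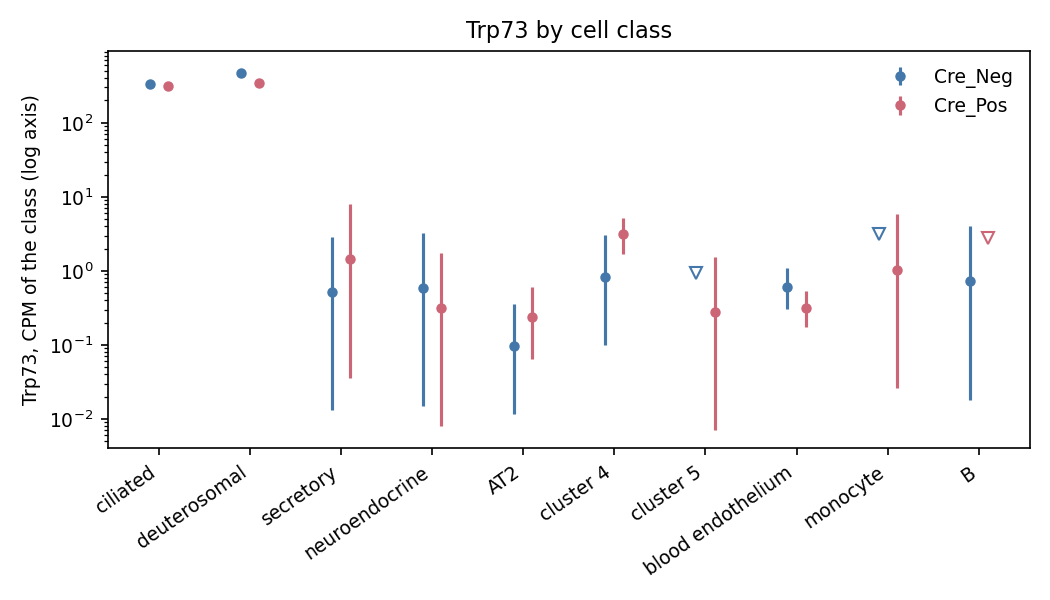
Trp73 level in CPM of the class (log axis) in each pool, with 95% intervals for counting error; open triangles mark the limit allowed by 0 counts. Ciliated-like cells were at 334 CPM in Cre_Neg and 316 CPM in Cre_Pos.

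Foxj1, a transcription factor of the motile cilia programme, was at 114 CPM in Cre_Neg and 15.6 CPM in Cre_Pos over all kept cells, and at 445 CPM (436 to 455) and 347 CPM (323 to 373) within ciliated-like cells. In deuterosomal-like cells Foxj1 was at 696 and 690 CPM. Shh, the gene whose regulatory sequence drives Cre, was detected in AT2-like cells with 200 UMIs in Cre_Neg and 125 in Cre_Pos, a log2 ratio of -0.38 (-0.72 to -0.05). Shh had 138 and 9 UMIs in ciliated-like cells, with a log2 ratio of -0.78 (-1.94 to 0.18), and 40 and 13 UMIs in secretory-like cells, with a log2 ratio of -0.17 (-1.20 to 0.76). Blood endothelium had 0 Shh UMIs in both pools.

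The next comparison asked whether the airway epithelium kept its multiciliated cells. Ciliated-like cells made up 15.6% (14.8 to 16.4) of the kept Cre_Neg cells and 1.36% (1.13 to 1.63) of the kept Cre_Pos cells, which was 11.4-fold lower (9.45 to 13.9). Of the airway cells, here the ciliated-, secretory- and deuterosomal-like classes, they were 83.7% (81.7 to 85.6; 1198 of 1431 cells) in Cre_Neg and 50.2% (43.6 to 56.8; 118 of 235 cells) in Cre_Pos. The share was 83.3%, 85.1%, 84.5% and 81.2% in the 4 Cre_Neg aliquots and 56.3%, 41.9%, 58.2% and 40.5% in the 4 Cre_Pos aliquots, with SDs of 1.75 and 9.30 percentage points that cover the technical spread of the aliquots and not the spread between animals. There were 7.35 ciliated-like cells per secretory-like cell in Cre_Neg and 2.46 in Cre_Pos, and 17.1 and 1.71 per deuterosomal-like cell. Deuterosomal-like cells were 70 in Cre_Neg and 69 in Cre_Pos, at median depths of 2361 and 1084 UMIs. Of these, 13 and 21 cells had UMIs of at least 3 deuterosomal markers, while all 70 and 69 had UMIs of at least 3 ciliated markers.

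The ciliated-like cells left in the Cre_Pos pool were almost all male by their transcripts. Among Cre_Pos ciliated-like cells, 100 had UMIs of Y-linked genes and none of Xist, the RNA that silences an X chromosome in females, and 2 had the reverse, so that 98.0% (93.1 to 99.8) of the calls were Y only, against 16.7% (14.5 to 19.1) in Cre_Neg. Y-only calls were 9.98% in Cre_Pos and 20.6% in Cre_Neg AT2-like cells, and 3.16% and 15.6% in blood endothelium. In secretory-like cells, Y-only calls were 73.7% of 19 calls in Cre_Pos and 16.7% of 84 in Cre_Neg, and Xist-only secretory-like cells numbered 5 and 70. Among Y-only cells, ciliated-like cells were 89.8% (84.8 to 93.7) of Cre_Neg airway cells and 82.6% (74.7 to 88.9) of Cre_Pos airway cells, and of all kept Y-only cells they were 177 of 1148 and 100 of 528. Among Xist-only cells they were 89.6% (87.5 to 91.5; 880 of 982 cells) in Cre_Neg and 6.45% (0.791 to 21.4; 2 of 31 cells) in Cre_Pos. The number of males and females in each pool is not given in the sources used here, and the 118 cells came from 21 of the 23 Cre_Pos wells that held cells. With the unnamed epithelial cluster 4 counted as airway, the ciliated-like share was 74.5% in Cre_Neg and 24.9% in Cre_Pos.

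**Figure D2:**
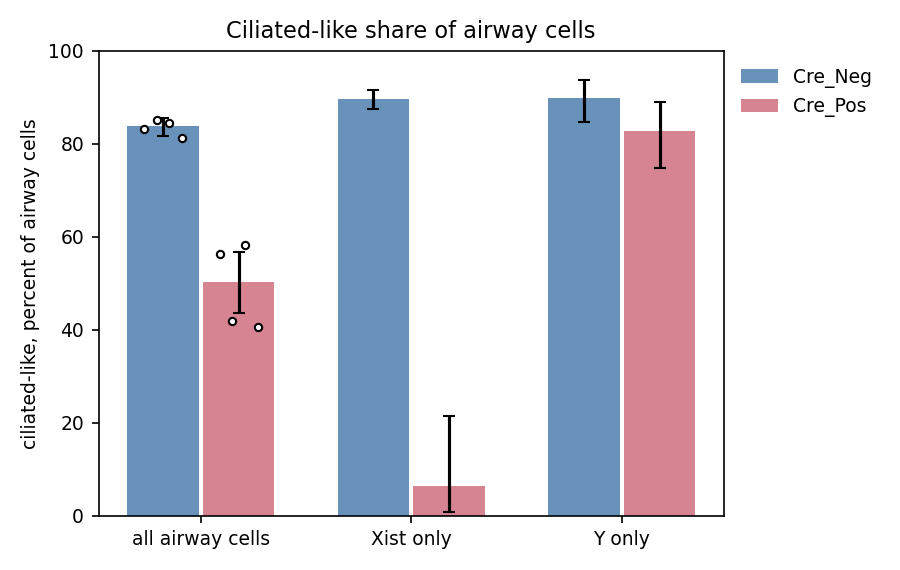
Ciliated-like cells as a percent of airway cells in each pool, for all cells and for cells with UMIs of Xist only or of Y-linked genes only; bars are the pools with exact 95% intervals, and open circles are the 4 sublibraries. Among Xist-only cells the share was 89.6% in Cre_Neg and 6.45% in Cre_Pos, and among Y-only cells 89.8% and 82.6%.

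The make-up of the pools was compared across all classes, with the CD45 depletion and EpCAM enrichment of each suspension setting part of every share. Blood endothelium was 35.1% (34.1 to 36.2) of Cre_Neg and 63.7% (62.7 to 64.7) of Cre_Pos cells, and epithelial cells together were 49.4% and 24.6%. AT2-like cells were 21.6% (20.6 to 22.5) and 12.6% (11.9 to 13.3) of kept cells, and 43.6% and 51.2% of epithelial cells. Secretory-like cells, the class of club and other secretory cells, were 2.12% and 0.554% of kept cells, 3.82-fold lower (2.75 to 5.39) in Cre_Pos, and 4.29% and 2.25% of epithelial cells, 1.90-fold lower (1.37 to 2.68). A cluster led by Bpifa1 and Muc5b held 78 of the 163 Cre_Neg and 22 of the 48 Cre_Pos cells of this class. Secretory-like cells were 70 of 5356 Cre_Neg and 5 of 7108 Cre_Pos cells among Xist-only cells. Among cells with UMIs of neither sex they were 78 of 903 and 27 of 739. Among Y-only cells they were 14 of 1148 and 14 of 528, where the share was not lower. Neuroendocrine-like cells were 1.57% and 1.95% of kept cells and 3.18% and 7.93% of epithelial cells, and cells with markers of the Krt8 transitional alveolar state were 1.00% and 1.06% of kept cells and 2.03% and 4.32% of epithelial cells, 2.13-fold higher (1.56 to 2.92) in Cre_Pos. Only 22 and 29 AT1-like cells were kept, too few for gene ratios. Among epithelial cells ciliated-like cells were 31.5% and 5.54%, 5.69-fold lower (4.71 to 6.93) in Cre_Pos. This fall by itself raises the epithelial shares of all other classes in Cre_Pos, among them the AT2-, neuroendocrine- and transitional-like cells. Of kept cells, the transitional share in Cre_Pos was 1.06 times that in Cre_Neg (0.776 to 1.46).

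Alveolar macrophages were 201 Cre_Neg cells and 3 Cre_Pos cells, 2.61% and 0.0346% of kept cells, and neutrophils were 59 and 4 cells. Both express CD45, the target of the depletion, and all other immune classes together were 7.82% of Cre_Neg and 6.59% of Cre_Pos cells. Within these, interstitial macrophages were 35 and 11 cells, 3.58-fold lower (1.78 to 7.82) in Cre_Pos, and plasma cells 24 and 8 cells, 3.38-fold lower (1.47 to 8.69). T cells were 0.962% and 1.52%, B cells 222 and 184 cells, monocytes 134 and 124 cells, and pericytes, the mural cells of capillaries, 0.260% and 0.947%. The clusters left unnamed were 3.30% and 2.83% of kept cells for cluster 5, 2.29% and 2.75% for cluster 4, 0.793% and 0.370% for cluster 32, 0.247% and 0.739% for cluster 38, 0.195% and 0.0808% for cluster 39, and 0.0130% and 0.208% for cluster 40.

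**Figure D3:**
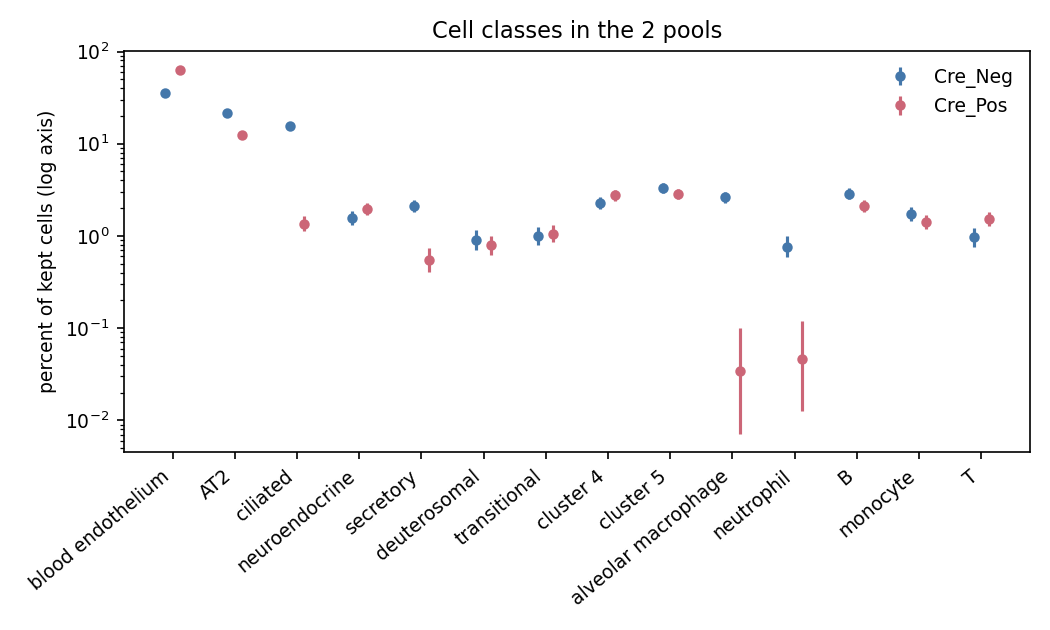
Cell classes as a percent of the kept cells of each pool (log axis), with exact 95% intervals for counting error. Blood endothelium was 35.1% in Cre_Neg and 63.7% in Cre_Pos, and ciliated-like cells 15.6% and 1.36%.

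In AT2-like cells the comparison asked how alveolar type 2 gene expression differed between the pools. Peak1, which encodes a pseudokinase of the cytoskeleton, was 4.46-fold higher in Cre_Pos, with 1652 UMIs in Cre_Neg and 6008 in Cre_Pos and a log2 ratio of 2.16 (2.08 to 2.24). Mfsd2a, a transporter of lysophospholipids, was higher by 1.73 (1.47 to 1.98) and Lrg1, a secreted glycoprotein, by 1.23 (1.06 to 1.41) on the log2 scale. Zbtb16, a zinc finger transcription factor that glucocorticoids induce, was 2.02-fold lower, with 20131 and 8135 UMIs and a log2 ratio of -1.01 (-1.05 to -0.98). Nr4a2 at -1.16, Sgk1 at -1.35 and Cyp2b10 at -1.02 were lower as well, the last a xenobiotic-metabolising cytochrome P450. The other genes named as higher were Syt2, Vwf, Pcdh11x, Gm13986, Kng2, Pigr and Prex2, with log2 ratios from 1.02 to 2.18. Those named as lower were Kcnb2, Ptprd, Hif3a, Gfra1, C330002G04Rik and 1600002D24Rik, from -2.58 to -1.06. Vwf and Prex2 are endothelial genes, and in barcodes with at most 50 UMIs, which hold free RNA, Vwf was at 146 CPM in Cre_Neg and 190 CPM in Cre_Pos, and Prex2 at 655 and 891 CPM. In AT2-like cells the fold differences were larger, at 4.53-fold for Vwf and 2.03-fold for Prex2, but the levels were low. Vwf was at 1.125 and 5.10 CPM there, and Prex2 at 4.11 and 8.34 CPM. The differences in CPM were thus smaller than those in the barcodes with at most 50 UMIs, and free RNA was not tested as their cause. Among Y-only AT2-like cells Peak1 stayed at 2.15, but Zbtb16 was at -0.32 (-0.56 to -0.09; 666 and 205 UMIs), Mfsd2a at 0.11 (12 and 5 UMIs) and Sgk1 near 0 (13 and 5 UMIs). In the same cells the log2 ratio turned negative for Lrg1 (-1.10; 89 and 16 UMIs), Kng2 (-2.53; 15 and 1 UMIs) and Pigr (-1.95; 30 and 3 UMIs), and positive for Kcnb2 (0.96; 4 and 3 UMIs), Hif3a (0.38; 4 and 2 UMIs) and C330002G04Rik (0.83; 41 and 28 UMIs). Without replicate 2, Vwf was at 1.42, Kcnb2 at -4.22 and Sgk1 at -1.94, and without replicate 3 Pcdh11x was at 2.70.

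Among the gene lists in AT2-like cells, 14 of 15 measured lipid synthesis genes were higher in Cre_Pos, with a median log2 ratio of 0.23, above all 10000 random lists matched on expression. Its highest member was Sqle (0.48), an enzyme of sterol synthesis, and its lowest were Dgat1 (-0.13) and Elovl1 (0.04). The NRF2 antioxidant list had a median of 0.14 at the percentile 99.9 of random lists, with Nqo1 at 1.88 from 6 and 18 UMIs and Srxn1 at 0.68 highest and Gstm1 and Gsta4 at -0.16 lowest. AT1 identity genes had a median of -0.14 at the percentile 0.29, with Col4a3, a basement membrane collagen, at -0.63 and Pdpn at -0.49 lowest and Scnn1g at 0.37 and Clic5 at 0.19 highest. Immediate early genes had a median of -0.16 at the percentile 0.02, with 14 of 17 members lower, among them Fosb (-0.52) and Nr4a1 (-0.40), and with Ier3 (0.59) and Hspa1a (0.14) highest. The ciliary axoneme and motor genes had a median of -0.49, below all random lists, with 16 of 20 members lower, Dnah9 (-1.01) and Dnah6 lowest, and Ccdc39 (0.39) and Tppp3 (0.06) highest. In the barcodes with at most 50 UMIs the same list made up 5325 CPM in Cre_Neg and 2663 CPM in Cre_Pos. Mitochondrially encoded genes had a median of -0.29 at the percentile 0.02, with mt-Nd4 at -0.45 and mt-Nd5 at -0.36 lowest and mt-Nd6 at 0.40 and mt-Nd1 at -0.20 highest. Surfactant and AT2 identity genes differed little, with a median of 0.05, Sftpc at -0.09, Ctsh at -0.29, Lpcat1 at 0.17 and Slc34a2 at 0.23. The sex-linked list had a median of -0.82, and 16 other measured lists, the surfactant list among them, lay between the percentiles 2.83 and 98.9 with medians from -0.20 to 0.23. Members of those lists that differed at least 2-fold were Fbn1 (1.84), Mki67 (1.46), Muc5b (-1.12), Cyp2b10 and Ccl20, the last of which had 26 UMIs in Cre_Neg and 0 in Cre_Pos. Among Y-only cells the medians were 0.00 for lipid synthesis, -0.16 for the NRF2 list and 0.05 for the AT1 list, so the last 2 turned sign.

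**Figure D4:**
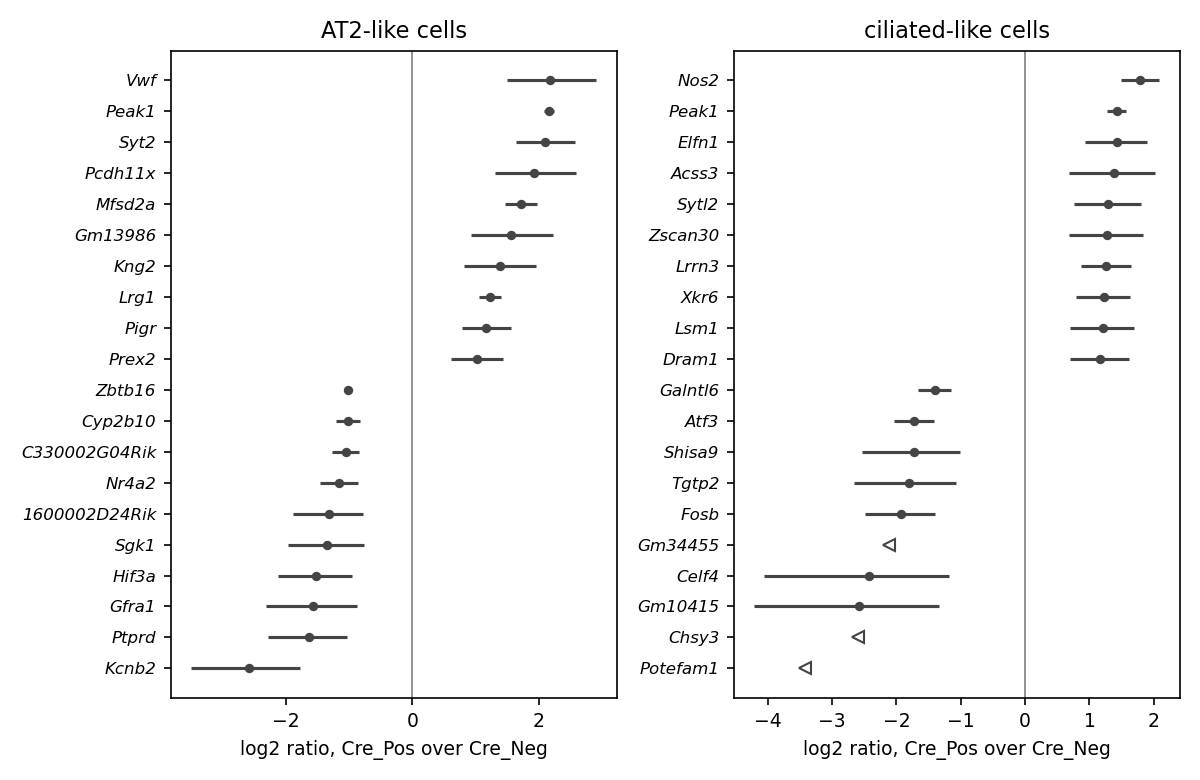
Log2 ratio, Cre_Pos over Cre_Neg, of the genes named in AT2-like (left) and ciliated-like cells (right), with 95% intervals for counting error; open triangles mark bounds set by 0 UMIs in Cre_Pos. Peak1 was higher in both classes, at 2.16 and 1.42.

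In ciliated-like cells the comparison asked whether the ciliated cells left in the Cre_Pos pool expressed their programme as those of Cre_Neg did. Ciliary axoneme and motor genes differed little, with a median log2 ratio of -0.08 at the percentile 0.76 of random lists and members from -0.22 (Cfap43) and -0.21 (Dnah12) to 0.07 (Dnah11) and 0.15 (Gas8), and a median of 0.07 among Y-only cells. Immediate early genes were lower, with a median of -0.82 and 16 of 17 members below 0, among them Fosb (-1.92), Atf3 (-1.72), Fos (-1.21), Dusp1 (-1.12), Nr4a1 (-1.07) and Jun (-1.05), and Hspa1b at 0.17 and Hspa8 at -0.02 highest. Nos2, the inducible nitric oxide synthase, was 3.46-fold higher in Cre_Pos, with 332 and 129 UMIs and a log2 ratio of 1.79 (1.49 to 2.09), and Peak1 was 2.68-fold higher, at 1.42 (1.27 to 1.57). Potefam1 was at least 10.7-fold lower, with 285 UMIs in Cre_Neg and 0 in Cre_Pos, Chsy3 at least 6.03-fold lower, with 161 and 0 UMIs, and Gm34455 at least 4.34-fold lower, with 116 and 0 UMIs, against a floor of 3 counts over the pool. Tgtp2, an interferon-induced GTPase, was at -1.80 (-2.65 to -1.07). The other genes named as higher were Elfn1, Lrrn3, Xkr6, Sytl2, Dram1, Lsm1, Acss3 and Zscan30, with log2 ratios from 1.17 to 1.42, and those named as lower were Gm10415, Celf4, Galntl6 and Shisa9, from -2.57 to -1.40. Galntl6 and Gm10415 were also leading genes of cluster 26, which held 4.92% of the Cre_Neg and 3.39% of the Cre_Pos ciliated-like cells. Only 2 Cre_Pos ciliated-like cells were Xist only, so the comparison within a sex covers Y-only cells, in which Nos2 was at 4.39, Tgtp2 at -3.21, Celf4 at 2.07 (2 and 5 UMIs) and Shisa9 at 0.07. In those cells Potefam1 had 11 and 0 UMIs and a bound of -1.13, Chsy3 30 and 0 UMIs and a bound of -2.57, and Gm34455 25 and 0 UMIs and a bound of -2.31. Without replicate 3, Nos2 was at 1.15, Celf4 at -4.42, Gm10415 at -1.80, and the bounds of Chsy3 and Gm34455 at -1.95 and -1.36. Without replicate 2, Atf3 was at -2.37 and Galntl6 at -2.07, and without replicate 1 Gm10415 was at -3.61. Thinned to 2000 UMIs per cell, Xkr6 was at -1.35.

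Other lists in ciliated-like cells rested on few Cre_Pos UMIs. AT1 identity genes had a median of 0.37 at the percentile 99.9, with Ager (1.91; 19 and 8 UMIs) and Rtkn2 (1.71; 30 and 11 UMIs) highest, Cav1 at 1.24 and Akap5 at 1.57, and Igfbp2 (-0.37) and Hopx (-0.02) lowest. The Krt8 transitional list had a median of 0.28 at the percentile 99.5, with Ndnf at 1.57, Hbegf at 0.83, Krt19 at -0.04 and Cdkn1a at -0.45, but -0.04 without replicate 3 and -0.10 among Y-only cells. MHC class II genes had a median of -0.82 at the percentile 0.305, with Ciita at -1.19, H2-Aa at -1.07, H2-Eb1 at -1.02, H2-Ab1 at -0.56 and H2-DMb1 at 1.88, and the median was -0.33 without replicate 1, -1.30 without replicate 3 and -2.68 among Y-only cells. Of the 5 measured collagen and fibrosis genes, Fn1 was at 1.76, Tgfb2 at 1.62, Tnc at 1.23, Col6a1 at -0.09 and Col6a2 at -1.17, a median of 1.23 over members that went both ways, which was 1.91 without replicate 2. Mitochondrially encoded genes had a median of -0.34, from mt-Nd6 at -0.91 and mt-Nd5 at -0.45 to mt-Nd4 at -0.21 and mt-Nd1 at -0.03, and the multiciliogenesis regulators a median of -0.06 at the percentile 28.8, with Ccno at 0.51 and Traf3ip1 at -0.01 highest, and Cdc20b at -1.55 and Gmnc at -1.91 from 67 and 2 UMIs. The sex-linked list had a median of 2.17, with Xist at -4.49 and Eif2s3y at 2.64. The 15 remaining lists, the multiciliogenesis list among them, lay between the percentiles 9.75 and 98.9. Their members at least 2-fold higher were Etv5, Bpifa1, Plk2, Tnfrsf10b, Zfp365, Ifit3, Mx1, Fmo2 and Fbn2, with log2 ratios from 1.02 to 3.03. Among Y-only cells the interferon response list, which holds Ifit3 and Mx1, had a median of -0.94 against 0.24 in all ciliated-like cells, and the NF-kB and chemokine list -0.95 against -0.16. Those at least 2-fold lower included Muc5b, Gtse1, Lcn2, Zbp1, Fbn1, Hmox1, Rrm2, Cenpf, Mcm2 and Boc, from -2.93 to -1.09.

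**Figure D5:**
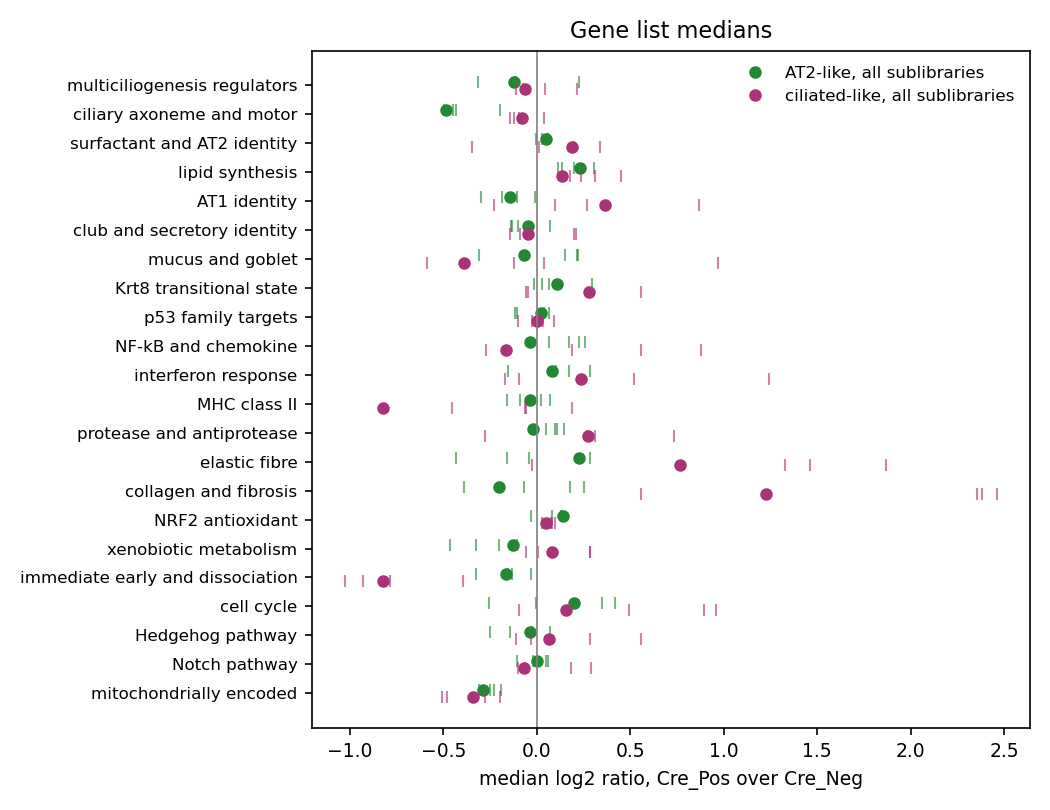
Median log2 ratio, Cre_Pos over Cre_Neg, of each gene list in AT2-like and ciliated-like cells; points are the pooled values and ticks the 4 sublibraries. Immediate early genes were at -0.82 in ciliated-like and -0.16 in AT2-like cells, and lipid synthesis genes at 0.23 in AT2-like cells.

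Blood endothelium, B cells and monocytes, in which Shh-Cre is not known to act, were compared in the same way. In blood endothelium all 17 immediate early and dissociation genes were higher in Cre_Pos, with a median log2 ratio of 0.57 and the heat shock genes Hspa1b (1.59) and Hspa1a (1.48) and the transcription factors Atf3 (1.46), Egr1 (1.42), Fosb (1.26) and Fos (1.10) highest. All 7 MHC class II genes were lower, with a median of -0.73, Cd74 at -1.43 (-1.51 to -1.34) and H2-DMb1 at -1.01, and 17 of 18 interferon response genes were lower, with Cxcl9 at -4.40 and Cxcl10 at -2.53. Cyp26b1, an enzyme that breaks down retinoic acid, was at -1.60 (-1.74 to -1.47), and Gm5127 at -2.87, while Gm26802 was at 2.32 (2.98 without replicate 2), Garin4 at 2.50 (3.17 without replicate 1) and Sdk2 at 2.54 (3.51 without replicate 1). Lipid synthesis genes had a median of -0.18, club and secretory genes -0.42, and ciliary genes -0.67, the last 2 being genes of airway cells. In monocytes interferon response genes had a median of -0.49, with Nr4a3 at 2.05, Osgin2 at 1.67, Anxa1 at -1.53, Cpq at -1.47 and Fosb at -1.04 among the named genes. In B cells Adgrf5 was at 2.72, but at 0.87 without replicate 1 and 3.53 without replicate 2. Other endothelial genes were higher in B cells as well, with Tek at 3.62, Ptprb at 3.29 and Cav1 at 4.85 (3 and 68 UMIs), the last at 5.24 in replicate 1 and between -1.35 and 1.00 in the others. Rell1 was at 1.90, Sox5 at -2.74, Robo1 at -4.30 (-2.88 without replicate 1 and -6.14 without replicate 4) and Lmo7 at -4.45 (-6.03 without replicate 1 and -3.69 without replicate 2). At the finer Leiden resolution the B cells fell into a cluster with Sox5 among its leading genes, which held 68 Cre_Neg and 8 Cre_Pos cells, and another with 154 and 176 cells, so these ratios also carry the mix of the clusters. MHC class II genes in monocytes had a median of 0.53, which was -0.23 without replicate 2.

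In neuroendocrine-like cells Kcnh1, a potassium channel gene, was at 3.12 (4.205 without replicate 2 and 2.46 without replicate 3) and Spp1 at 2.60, while Cntn5 was at -2.40 (-3.30 without replicate 3), Sgcd at -1.42 and Plxna4 at -1.28. Kcnh1 was also a leading gene of a blood endothelium cluster and Spp1 of the unnamed cluster 38. Whether RNA of those cells sets their ratios was not tested. At the finer resolution neuroendocrine-like cells formed a cluster with 45 Cre_Neg and 108 Cre_Pos cells and another with 76 and 61, so these ratios also carry the mix of the clusters. Cluster 5, which had AT2 markers together with Ndnf and Areg among its leading genes, showed Slc26a4, another of its leading genes, at 2.15 (0.95 without replicate 4) and Bmpr1b at 1.39, with Ankfn1 at -1.73, Gm34455 at -1.34 and Zbtb16 at -1.11, close to the Zbtb16 ratio of AT2-like cells. In cluster 4, which had AT2 markers together with the club cell genes Scgb1a1, Cyp2f2 and Hp among its leading genes, Chia1, an acidic chitinase, was at 3.53 (3.23 to 3.84), 4930412B13Rik at 3.70 (2.94 without replicate 2) and Tnxb at 4.10 (5.03 without replicate 1). Spon1 was at -3.65 (-4.71 without replicate 2) and Hs6st3 at -3.11 (-3.73 without replicate 1) in that cluster. At the finer resolution cluster 4 parted into a cluster led by Scgb1a1, with 131 Cre_Neg and 83 Cre_Pos cells, and a cluster led by 4930412B13Rik and Chia1, with 45 and 155 cells, so its ratios carry the mix of the 2 clusters. They may also carry the sex mix, since Y-only calls were 9.55% in Cre_Neg and 20.4% in Cre_Pos.

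Genes were then compared across the 8 classes with enough cells, to see which ratios were shared by classes inside and outside the epithelium. Peak1 was higher in Cre_Pos in all 8, with log2 ratios of 1.00 (0.94 to 1.06) in blood endothelium, 1.11 in B cells, 1.84 in monocytes, 1.85 in cluster 5, 2.00 in cluster 4 and 2.55 in neuroendocrine-like cells beside those of AT2- and ciliated-like cells. Without replicate 4 it was at 0.81 in monocytes and 1.91 in neuroendocrine-like cells. Of the 5819 genes measured in all 8 classes it ranked first by the ratio nearest 0. Mitochondrially encoded genes had medians below 0 in all 8 classes, among them -0.31 in blood endothelium, -0.32 in cluster 5, -0.50 in cluster 4, -0.33 in neuroendocrine-like cells, -0.46 in monocytes and -0.76 in B cells. Tek and Ptprb, endothelial receptor genes, were higher by 0.33 and 0.12 in blood endothelium, by 0.53 and 1.26 in AT2-like cells and by 3.62 and 3.29 in B cells. Endothelium was 35.1% of Cre_Neg and 63.7% of Cre_Pos cells, and whether that share sets these ratios was not tested.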

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

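The tests of explanations in this part were chosen after the results they address had been seen. Of 73 values checked over the 4 sublibraries, 3 had a sublibrary far from the others, and chance alone marks about 1 in 20 such groups. Kept Cre_Neg cells were 1472 in sublibrary 4 and 2056 to 2093 in the others, and kept Cre_Pos cells were 1649 there and 2294 to 2392 in the others. The median of the collagen and fibrosis list in ciliated-like cells was 0.56 in sublibrary 1 and 2.36 to 2.46 in the others, where 5 members and the floor of 3 counts set the value. Of 12 values compared between the sexes, Lrg1 in AT2-like cells had a log2 ratio of -1.10 among Y-only cells and 1.35 among Xist-only cells, with opposite signs in all 4 sublibraries; this difference was not tested.

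Ciliated-like cells were 15.6% of Cre_Neg and 1.36% of Cre_Pos cells. Fewer airways in the Cre_Pos suspension are argued against as the whole cause, since ciliated-like cells per deuterosomal-like cell differed 10.0-fold between the pools and numbered 7.35 and 2.46 per secretory-like cell. Fewer airways could still be a part, as Xist-only secretory-like cells fell from 70 to 5, and the deuterosomal-like cells differed in depth with only 13 and 21 of them having UMIs of 3 deuterosomal markers. Loss of ciliated cells to the filters is also argued against as the whole cause, since Trp73 was 5.41-fold lower in Cre_Pos over all barcodes. That value largely repeats the kept cells, which held 6890 of 7524 Trp73 UMIs in Cre_Neg and 1023 of 1510 in Cre_Pos. It rests on the targeted gene and does not cover cells lost before barcoding. In barcodes with at most 50 UMIs the ciliary axoneme and motor list differed less, at 5325 and 2663 CPM. Handling that met all cells of the pooled Cre_Pos suspension alike is argued against as the whole cause. Among Y-only cells, ciliated-like cells were 89.8% of Cre_Neg and 82.6% of Cre_Pos airway cells, and among Xist-only cells 89.6% and 6.45%. Deletion of Trp73 may be the cause. With 1 pool per genotype it cannot be told apart from other differences between the animals or in their handling before pooling.

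The ciliated-like cells left in the Cre_Pos pool had Y-linked UMIs. Cre_Neg cells that carry Cre_Pos barcodes are argued against, since 98.0% of the sex calls were Y only and 16.7% of those in Cre_Neg ciliated-like cells. A hypothesis is that male animals of the Cre_Pos pool kept ciliated cells: among Y-only cells the ciliated-like share of airway cells was 7.20 percentage points lower in Cre_Pos, while their share of ciliated- and AT2-like cells together was higher there, at 49.8% against 36.2%. An animal without the Cre allele in the Cre_Pos pool could give the same values and cannot be told apart: Peak1 had a log2 ratio of 1.86 in the Y-only ciliated-like cells, which would speak against it only if Peak1 followed the animals and not the handling of the suspension.

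Peak1 was higher in Cre_Pos in all 8 classes. Free RNA is argued against as the whole cause, since the smallest difference over the classes was 133 CPM and that in barcodes with at most 50 UMIs was 90.7 CPM. The sex make-up of the pools is argued against, since the log2 ratio was 2.12 in Xist-only and 2.15 in Y-only AT2-like cells. Deletion of Trp73 in cells of the Shh-Cre lineage is argued against as the whole cause, since the lowest log2 ratio over blood endothelium, B cells and monocytes was 1.00. A difference between the animals or the suspensions of the 2 pools stays open and was not tested.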

How the results depend on the processing

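No paired analysis was possible because there was 1 pool per genotype and no result comes from a test. Of the values under settings fixed beforehand, 2441 stayed within their spread, 240 moved beyond it, some whose interval had spanned 0 changing sign, and 4 with a clear sign turned it; of those under settings chosen after seeing the data, 161 stayed, 63 moved and 14 turned sign. Leaving out 1 sublibrary or rescaling uses most or all of the same counts as the main value, so such values tend to stay by construction. The totals are therefore no measure of how the results would hold in other animals. Unless stated otherwise the cause of a move was not tested. At Leiden resolution 2 the log2 ratio of the AT2-like share was -0.65 and of the deuterosomal-like share 0.31, and the Cre_Neg ciliated-like share of airway cells was 85.6% (83.8% and 52.6% in Cre_Neg and Cre_Pos at resolution 0.5). From 1000 genes per cell the deuterosomal-like ratio was -0.73 and the airway shares 89.1% and 66.1% in Cre_Neg and Cre_Pos, fewer shallow cells being left by construction. The Cre_Neg airway share was 86.8% at 5% mitochondrial UMIs, and the airway shares were 78.2% and 39.2% by markers after thinning, 89.6% and 6.45% in Xist-only cells, 89.8% and 82.6% in Y-only cells, and 74.5% and 24.9% with cluster 4. The Trp73 log2 ratio over all kept cells was -3.04 to -2.71 without a sublibrary and -2.44 over all barcodes. Leaving out a sublibrary gave medians of -0.61 to -0.35 for ciliary genes in AT2-like cells, -0.0409 to 0.44 for the Krt8 list and -1.30 to -0.33 for MHC class II in ciliated-like cells, and -0.23 to 0.82 for MHC class II in monocytes. Thinned cells gave -1.35 for Xkr6, -0.0696 for the Krt8 list and -0.48 for immediate early genes in ciliated-like cells, and -0.38 for mitochondrially encoded genes in AT2-like cells; without doublet removal MHC class II in ciliated-like cells was at -0.25. Y-only AT2-like cells gave -1.10 for Lrg1, -2.53 for Kng2, -1.95 for Pigr, 0.96 for Kcnb2, 0.38 for Hif3a, 0.83 for C330002G04Rik, 0.0014 for lipid synthesis, 0.0549 for AT1 identity, -0.16 for NRF2, -0.70 for immediate early and 0.0417 for sex-linked genes. Y-only ciliated-like cells gave 2.07 for Celf4, 0.0703 for Shisa9, 0.0665 for ciliary genes, -0.10 for the Krt8 list, -2.68 for MHC class II and -0.000406 for sex-linked genes, the 2 sex-linked medians following from the choice of cells. The endothelial share kept its direction under all 9 alternatives, with log2 ratios from 0.81 to 0.88, as did the ciliated-like share, from -3.66 to -3.39; neither was run by sex, but ciliated-like cells were 880 of 5356 Cre_Neg and 2 of 7108 Cre_Pos cells among Xist-only cells and 177 of 1148 and 100 of 528 among Y-only cells, where the share was not lower in Cre_Pos. Depth limits the ciliated-like comparison, in which the Cre_Pos pool had 118 cells.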

Other observations

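Cluster 4, with AT2 and club cell markers, differed between the pools in several lists, which also carries the mix of its cells: at the finer resolution 131 Cre_Neg and 83 Cre_Pos cells fell into a cluster led by Scgb1a1, and 45 and 155 into one led by 4930412B13Rik and Chia1. The sex mix differed as well, with Y-only calls at 9.55% of 157 calls in Cre_Neg and 20.4% of 216 in Cre_Pos. The values below cover both sexes together. In Cre_Pos, 14 of 15 club and secretory genes were lower, with a median log2 ratio of -0.73, Scgb1a1 at -1.25 and Bpifb1 at -2.46. The Krt8 transitional list had 17 of 18 members higher, with a median of 0.64 and Lgals3 at 2.05, S100a6 at 1.66, Cdkn1a at 1.63 and Areg at 1.37. Surfactant genes had a median of 0.43, lipid synthesis genes 0.49, p53 family targets 0.49, and the NF-kB and chemokine list 0.47. Xenobiotic metabolism genes had a median of -0.43 and Notch pathway genes -0.41. Gclc, which encodes the catalytic subunit of the rate-limiting enzyme of glutathione synthesis, was at 1.18, and Gmnc, a regulator of multiciliated cell fate, at 1.24 with 35 and 156 UMIs. Trp73 had 2 UMIs in Cre_Neg and 14 in Cre_Pos in this cluster, a log2 ratio of 1.90 (-0.23 to 5.08).

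In cluster 5, which had AT2 markers with Ndnf and Areg, lipid synthesis genes had a median of 0.22 and all 8 measured NF-kB and chemokine genes were higher, with a median of 0.34, while xenobiotic metabolism genes had a median of -0.45. In neuroendocrine-like cells lipid synthesis genes had a median of 0.25 and NRF2 antioxidant genes 0.28, medians that also carry the mix of their clusters at the finer resolution. Outside the airway, Trp73 had 15 UMIs in the 24 Cre_Neg and 9 UMIs in the 8 Cre_Pos plasma-like cells, 47.1 and 84.1 CPM. In proliferating-like cells it had 15 UMIs, from 6 of 40 cells, in Cre_Neg and 0 in the 27 Cre_Pos cells. That gave a log2 bound of -1.37 at the floor of 3 counts. Among Xist-only deuterosomal-like cells, 32 in Cre_Neg and 24 in Cre_Pos, Trp73 was at 558 and 322 CPM, at median depths of 3150.5 and 19533 UMIs, and among the 6 and 7 Y-only cells at 289 and 526 CPM. Of the Xist-only cells, 9 and 14 had UMIs of at least 3 deuterosomal markers.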
